A study of Mus musculus with 75 samples.

How the data were processed

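The series holds RNA sequencing of gastrocnemius muscle from male and female mice in 10 groups, defined by sex and by treatment with PBS and saline, C26 cells and saline, or C26 cells and 5-fluorouracil, paclitaxel or cisplatin. Total RNA was extracted with TRIzol and a column kit and sequenced on an Illumina instrument with paired ends, per the labels' protocols. The deposited table gives 1 log2 expression value per gene and library. FastQC, MultiQC, fastp, Salmon, edgeR and limma, and the mouse build mm39 (GRCm39), are named in the submitters' processing notes, without versions or roles, and the filter on low genes and the scaling of libraries are not given in the sources used here. From the values themselves, the authors' log2 values have the form log2 of an estimated count plus 0.5, divided by a scaled library size. Solving for the library size gave 11.4 to 40.5 M estimated counts per library, and 85.0 to 90.7% of a library's values came out within 0.02 of a whole number. Back-transformed values summed to 0.832 to 1.34 M per library, so the authors' scaling differs from plain division by the total. Count tests were not run, because the recovered counts are estimates.

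The labels list 75 samples. The table has 74 columns of values, and 1 female PBS saline library (replicate 8) was not analysed here. A further female library was left out of every comparison because its title names saline while its treatment label names 5-fluorouracil. This left 73 libraries, with groups taken from the titles and treatment labels. The planned fit of 74 libraries therefore held 73, with 63 residual degrees of freedom. The labels give every library the same batch value. Nothing in the labels says more about how animals were housed or processed together, so p values measure the spread between these samples. No pair of libraries agreed within counting noise. The closest pair within a group, male PBS replicates 2 and 4, differed by a mean chi-square of 14.9 per gene.

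All 13856 genes of the table were tested. Of these, 311 had no symbol in the table, and 288 were named by gene ID from the GENCODE vM21 annotation (GRCm38), which was also used for transcript GC content and length. In all, 13791 gene IDs (99.5%) matched it. No coordinates are given, because the builds differ. limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend) fitted the mean of each group to all libraries at once, so that the groups share 1 estimate of spread per gene. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. There were 25 comparisons, 8 of them main (tumour against PBS and each drug against C26 saline, in each sex), with 4 interactions between sex and treatment. The groups, tests, gene lists, rule for named genes and other settings were fixed before the data were examined.

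Of 48 gene lists, 44 had at least 5 measured members and were tested with camera in limma, at a preset correlation between genes of 0.01 and again with the correlation estimated from the data. Adjustment was over the lists of a comparison. Named genes were, in each main comparison, the 6 largest rises and 6 largest falls among called genes with a mean log2 value of at least 1 and a symbol that is not a predicted model, up to 4 members of each list with the smallest adjusted p, and 15 genes fixed for their roles in wasting. In other comparisons they were the 5 genes with the smallest p. The sex labels were checked with 4 Y-linked genes. Genes with near-identical copies are uncertain, since Salmon divides shared reads between copies.

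The GC slope of a library is the slope of its genes' deviations from their means on standardised transcript GC content, with log2 length as a second regressor, over 10637 genes with a mean of at least 1. The mitochondrial share is the percent of back-transformed expression in 13 mitochondrially encoded genes. The settings planned besides were quantile normalization, a mean log2 value of at least 1, only the groups compared, quality weights (arrayWeights in limma), a replicate block, leaving out each library in turn and the estimated correlation. Another pseudocount and DESeq2 were listed but not run, since the table holds log2 values and no counts. After the GC slopes had been seen, 2 alternatives were added: the slope as a covariate, and a fit without the 19 libraries above a slope of 0.1, a limit also chosen then. A sign change of a result that was called in neither setting was taken as no change.

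To compare drug and tumour effects without shared libraries, the C26 saline libraries were divided between the effects in 100 random draws, and unchanged groups were simulated the same way. The spread given is the SD over draws. The agreement between sexes has a jackknife standard error over libraries. Each count of genes was recomputed for 100 splits of the same libraries into groups of the same sizes. Libraries apart from their group were searched among the 15 fixed genes and library measures with Dixon's test.

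The fits were tested on normal values simulated from each gene's mean and residual SD, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among 13856. In female C26 saline against PBS 43.3% of 1.5-fold and 91.0% of 2-fold changes were recovered, and 6.63% of called genes were false. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the values and drew the figures.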

Results

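RNA sequencing measured gene expression in the gastrocnemius, a calf muscle of mostly fast fibres, of male and female BALB/c mice. The mice carried tumours of C26 cells, a mouse colon carcinoma line whose tumours waste muscle, or had been injected with phosphate-buffered saline (PBS). From day 12, tumour-bearing mice received saline or a chemotherapy drug at 75% of its maximum tolerated dose in 2 cycles, and the muscle was taken at day 25. 5-Fluorouracil is a pyrimidine analogue that blocks thymidylate synthesis, paclitaxel stabilises microtubules, and cisplatin crosslinks DNA. The design asks how the tumour alone, and each drug in tumour-bearing mice, changed the muscle transcriptome of each sex.

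The 10 groups held 73 libraries. In females there were 7 PBS, 7 C26 saline, 8 5-fluorouracil, 7 paclitaxel and 6 cisplatin libraries. In males there were 8 PBS, 8 C26 saline, 8 5-fluorouracil, 6 paclitaxel and 8 cisplatin libraries. Estimated counts recovered from the deposited log2 values summed to 11.4 to 40.5 M (M for mega) per library (median 22.5 M). Log2 changes are the first-named group minus the second, with the standard error of the limma estimate after ±, and a direction counted in libraries means beyond the mean of the second group. Adjusted p values of genes come from limma and those of gene lists from camera, over 13856 genes.

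Y-linked genes followed the labels. In the 8 male PBS libraries Ddx3y, an RNA helicase, lay at 5.64 ± 0.52 (SD, log2), Eif2s3y at 5.38 ± 0.35, Kdm5d at 3.70 ± 0.19 and Uty at 2.85 ± 0.67, and all 4 were listed at 0 counts in the 7 female PBS libraries. Of the other female libraries, 1 paclitaxel and 2 cisplatin libraries held reads of Kdm5d, at most at -3.90, while no male library lay below 2.45. Xist was not analysed here.

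Libraries within groups differed in how expression followed the GC content of transcripts. The slope of a library's deviation on GC content (log2 units per standard deviation of GC content) averaged 0.27 ± 0.26 (SD) in male paclitaxel and 0.12 ± 0.26 in male 5-fluorouracil, against -0.11 ± 0.06 in male C26 saline and -0.09 ± 0.15 in male PBS. In females the means lay between -0.15 ± 0.06 in cisplatin and 0.04 ± 0.27 in paclitaxel, with 0.01 ± 0.21 in C26 saline and -0.03 ± 0.18 in PBS. In 19 libraries the slope exceeded 0.1, among them 4 of 6 male paclitaxel, 4 of 8 male 5-fluorouracil and 0 of 8 male C26 saline libraries. Transcripts encoded by mitochondrial DNA took a median of 2.59% of expression in those 19 libraries and 10.5% in the others. By group this share averaged 5.24 ± 4.90% (SD) in male paclitaxel, 6.89 ± 4.42% in male 5-fluorouracil, 9.37 ± 3.73% in male C26 saline and 10.4 ± 3.60% in male PBS.

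**Figure D1:**
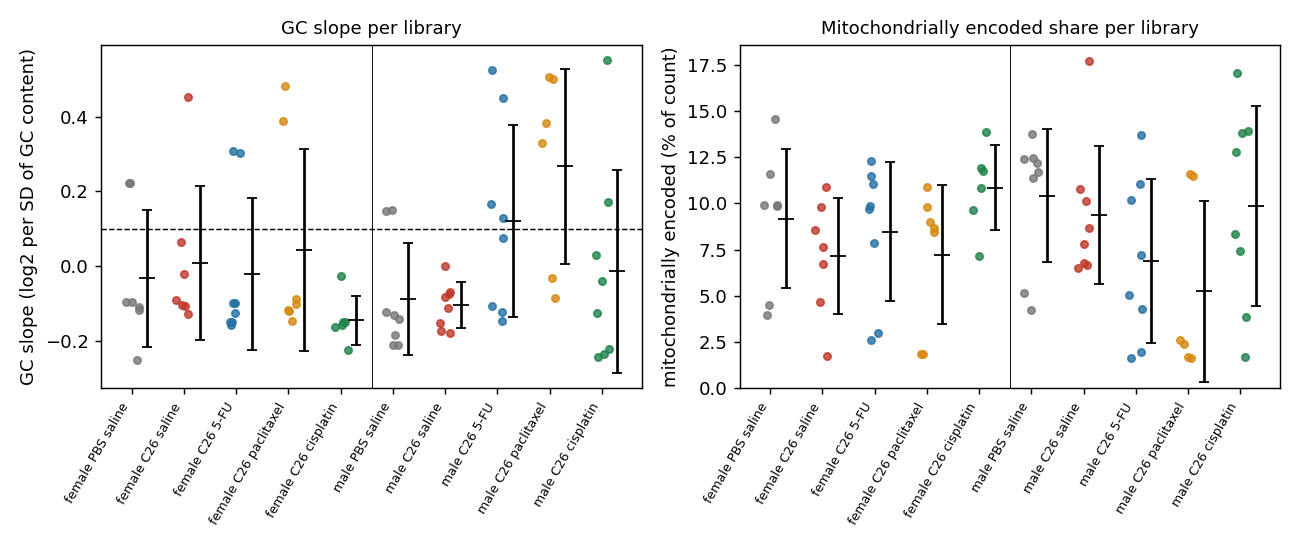
GC slope (log2 units per SD of transcript GC content) and percent of expression from mitochondrially encoded transcripts, 1 point per library, by group; the dashed line marks the slope of 0.1. Of the 19 libraries above the line, 4 are from male paclitaxel and 4 from male 5-fluorouracil, and none is from male C26 saline or female cisplatin.

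The tumour alone raised acute-phase transcripts in female muscle (7 C26 saline versus 7 PBS libraries). Serpina3n (ENSMUSG00000021091), an acute-phase inhibitor of serine proteases, rose by 4.04 ± 0.42 (adjusted p = 4.65e-10), and Mt2 (ENSMUSG00000031762), a metallothionein that binds zinc, rose by 3.90 ± 0.64 (adjusted p = 1.72e-05). Lcn2, which binds bacterial siderophores, rose by 3.77 ± 0.64, and Socs3, the feedback inhibitor of STAT3, by 3.15 ± 0.54 (adjusted p = 3.49e-05 and 3.95e-05). For these 4 genes all 7 C26 libraries lay above every PBS library. Stat3 itself rose by 1.48 ± 0.21, the lipopolysaccharide-binding protein Lbp by 2.38 ± 0.31, the glucocorticoid-induced cochaperone Fkbp5 by 2.47 ± 0.34 and the transcription factor Foxo1 by 1.84 ± 0.43, each in 7 of 7 libraries. Among genes that fell were the muscle nicotinamide riboside kinase Nmrk2 (-2.04 ± 0.49), the transferrin receptor Tfrc (-2.12 ± 0.57), the transcriptional repressor Bcl6b (-2.12 ± 0.32) and the immunoglobulin heavy chain Ighm (-2.60 ± 0.64). Fbxo32 (ENSMUSG00000022358) and Trim63 (ENSMUSG00000028834), the muscle ubiquitin ligases atrogin-1 and MuRF1, did not pass, at 1.04 ± 0.41 (adjusted p = 0.125) and 1.048 ± 0.47 (adjusted p = 0.195). Both passed when libraries were weighted by quality, and Trim63 also with the compared groups fitted alone. Mt1 and Mt2, the Serpina3 genes and the immunoglobulin genes have close copies that share reads, so the split of reads between copies is uncertain here and below.

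By list, of the IL-6/STAT3 and acute-phase genes 23 of 31 rose and 0 fell (23 and 1 adjusted over the list alone, median 1.70, adjusted p = 7.87e-30, or 0.000153 with an estimated correlation). Of the neutrophil markers 9 of 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 2.93, adjusted p = 4.08e-14, or 0.0227 with an estimated correlation). The neutrophil collagenase Mmp8 rose by 3.45 ± 0.71 and the receptor of granulocyte colony-stimulating factor Csf3r by 2.38 ± 0.49. Of the macrophage markers 12 of 20 rose and 0 fell (16 and 0 adjusted over the list alone, median 0.96, adjusted p = 5.4e-15, or 0.108 with an estimated correlation), with complement C1qb at 1.21 ± 0.27 and the Fc receptor Fcgr3 at 1.35 ± 0.21. Of the FoxO and glucocorticoid targets 10 of 26 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.57, adjusted p = 8.39e-07, or 0.42 with an estimated correlation), among them the phosphatidate phosphatase Lpin1 (0.86 ± 0.17). Of the cytosolic ribosomal proteins 11 of 77 rose and 0 fell (32 and 0 adjusted over the list alone, median 0.39, adjusted p = 2.21e-19, or 0.309 with an estimated correlation), with Rpl3 at 0.93 ± 0.19. Of the antioxidant NRF2 list 5 of 23 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.18, adjusted p = 0.00224, or 0.193 with an estimated correlation), with the extracellular glutathione peroxidase Gpx3 at 1.22 ± 0.22. Of the metal and iron handling genes 5 of 17 rose and 1 fell (5 and 1 adjusted over the list alone, median 0.13, adjusted p = 0.087, or 0.42 with an estimated correlation).

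Smaller shifts passed camera in females for proteasome subunits, with a median of 0.17 (adjusted p = 0.000113, or 0.42 with an estimated correlation), autophagy and lysosome genes, with 0.14 (adjusted p = 0.00403, or 0.42 with an estimated correlation), and tricarboxylic acid cycle genes, with -0.13 (adjusted p = 0.00545, or 0.722 with an estimated correlation). The last call was lost without the 19 libraries of high GC slope (adjusted p = 0.0694). In all, 573 genes rose and 355 fell. The count of 928 became 538 without C26 saline replicate 6, 1931 with the GC slope as a covariate, 1654 without the libraries of high slope and 2047 with quality weights.

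In males (8 versus 8 libraries) the tumour raised acute-phase genes together with the atrophy ligases. Lcn2 rose by 6.75 ± 0.60 (adjusted p = 2.73e-13), Mt2 by 6.30 ± 0.59 (adjusted p = 2.55e-12) and Serpina3n by 4.72 ± 0.40 (adjusted p = 3.8e-14). Fbxo32 rose by 2.21 ± 0.38 (adjusted p = 7.23e-06), from 8.11 ± 0.30 to 10.32 ± 0.86 (SD, log2), and Trim63 by 2.45 ± 0.44 (adjusted p = 1.32e-05), from 8.06 ± 0.29 to 10.51 ± 0.93. The cell cycle inhibitor Cdkn1a rose by 2.74 ± 0.42 (adjusted p = 5.75e-07). All 8 C26 libraries lay above every PBS library for these 6 genes. The zinc importer Slc39a14 rose by 2.39 ± 0.26 and the translation repressor Eif4ebp1 by 2.39 ± 0.35. Casq1, the calcium store protein of fast fibres, fell by 2.08 ± 0.24, and the light chain Myl1 by 1.36 ± 0.19, and the calcium buffer Pvalb lay at -1.495 ± 0.21. Nmrk2 fell by 3.76 ± 0.46, the muscle phosphatase Dusp29 by 3.37 ± 0.41, the clock output gene Dbp by 2.76 ± 0.38 and Ighm by 5.46 ± 0.59.

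By list, of the IL-6/STAT3 and acute-phase genes 26 of 31 rose and 1 fell (26 and 1 adjusted over the list alone, median 2.01, adjusted p = 4.84e-22, or 0.00207 with an estimated correlation). Of the neutrophil markers 10 of 10 rose and 0 fell (10 and 0 adjusted over the list alone, median 2.82, adjusted p = 1.1e-08, or 0.132 with an estimated correlation), and of the macrophage markers 14 of 20 rose and 0 fell (15 and 0 adjusted over the list alone, median 1.02, adjusted p = 4.55e-09, or 0.191 with an estimated correlation). Of the proteasome subunits 22 of 32 rose and 0 fell (22 and 0 adjusted over the list alone, median 0.42, adjusted p = 1.5e-11, or 0.132 with an estimated correlation), with the ATPase subunit Psmc2 at 0.71 ± 0.10 and the core subunit Psma7 at 0.88 ± 0.14. Of the autophagy and lysosome genes 18 of 33 rose and 0 fell (20 and 0 adjusted over the list alone, median 0.27, adjusted p = 2.39e-06, or 0.135 with an estimated correlation), with Map1lc3b, which marks autophagosomes, at 1.21 ± 0.18 and cathepsin L (Ctsl) at 1.58 ± 0.23. Of the FoxO and glucocorticoid targets 15 of 26 rose and 0 fell (17 and 0 adjusted over the list alone, median 1.15, adjusted p = 6.72e-10, or 0.191 with an estimated correlation), with Foxo1 at 2.14 ± 0.40. Of the muscle ubiquitin ligases and atrophy genes 8 of 23 rose and 2 fell (9 and 3 adjusted over the list alone, median 0.33, adjusted p = 0.0324, or 0.383 with an estimated correlation), and this call was lost with the GC slope as a covariate (adjusted p = 0.0564). Of the unfolded protein response genes 9 of 20 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.45, adjusted p = 2.47e-05, or 0.191 with an estimated correlation), with the transcription factor Xbp1 at 0.79 ± 0.12. The ribosomal proteins had a median of 0.29 (adjusted p = 1.55e-06, or 0.564 with an estimated correlation).

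Energy metabolism and contraction genes moved the other way in males. Of the nuclear genes of oxidative phosphorylation 0 of 77 rose and 22 fell (0 and 24 adjusted over the list alone, median -0.31, adjusted p = 1.57e-07, or 0.564 with an estimated correlation), with the complex I subunit Ndufc1 at -0.57 ± 0.15. Of the tricarboxylic acid cycle genes 0 of 22 rose and 8 fell (0 and 11 adjusted over the list alone, median -0.31, adjusted p = 0.00053, or 0.493 with an estimated correlation), with Idh3a at -0.71 ± 0.13. Of the glycolysis and glycogen genes 3 of 28 rose and 12 fell (3 and 13 adjusted over the list alone, median -0.26, adjusted p = 0.0101, or 0.493 with an estimated correlation), with the phosphorylase kinase subunit Phkg1 at -0.997 ± 0.15. Of the fast fibre genes 1 of 18 rose and 7 fell (1 and 8 adjusted over the list alone, median -0.26, adjusted p = 0.000173, or 0.406 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.109). Of the interferon response genes 0 of 36 rose and 7 fell (0 and 6 adjusted over the list alone, median -0.34, adjusted p = 0.00606, or 0.574 with an estimated correlation), with the guanylate-binding protein Gbp3 at -2.11 ± 0.39. That call was lost without the libraries of high GC slope (adjusted p = 0.0794). In all, 1811 genes rose and 1806 fell, and no left-out library moved the count of 3617 below 3047. All 3617 were among the 5624 genes called with the GC slope as a covariate.

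The sexes were set against each other by an interaction term, the male minus the female tumour effect. limma called 5 genes, and 1132 had an unadjusted p under 0.05. The serine protease gene Htra4 (-2.76 ± 0.49, adjusted p = 0.00583) and the nuclear receptor Nr4a2 (2.53 ± 0.48, adjusted p = 0.00754) were among them, and Fbxo32 and Trim63 were not. The count was 0 with a mean log2 value of at least 1, 10 with the compared groups alone, 33 with the GC slope as a covariate and 255 with quality weights. It was 3 without male C26 saline replicate 1 or 6, 11 without female C26 saline replicate 1, 18 without female C26 saline replicate 6, 15 without male C26 saline replicate 8 and 102 without male C26 saline replicate 4. Proteasome subunits had a median interaction of 0.26 (adjusted p = 1e-08, or 0.24 with an estimated correlation), and nuclear oxidative phosphorylation genes of -0.29 (adjusted p = 1e-08, or 0.44 with an estimated correlation). Across all 13856 genes, which are not independent replicates, the effects in the sexes correlated at r = 0.675 (rho = 0.646, jackknife SE 0.0904). In both sexes 471 genes rose and 280 fell, where independent lists would share 74.9 and 46.3, and 1 gene went opposite ways.

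**Figure D2:**
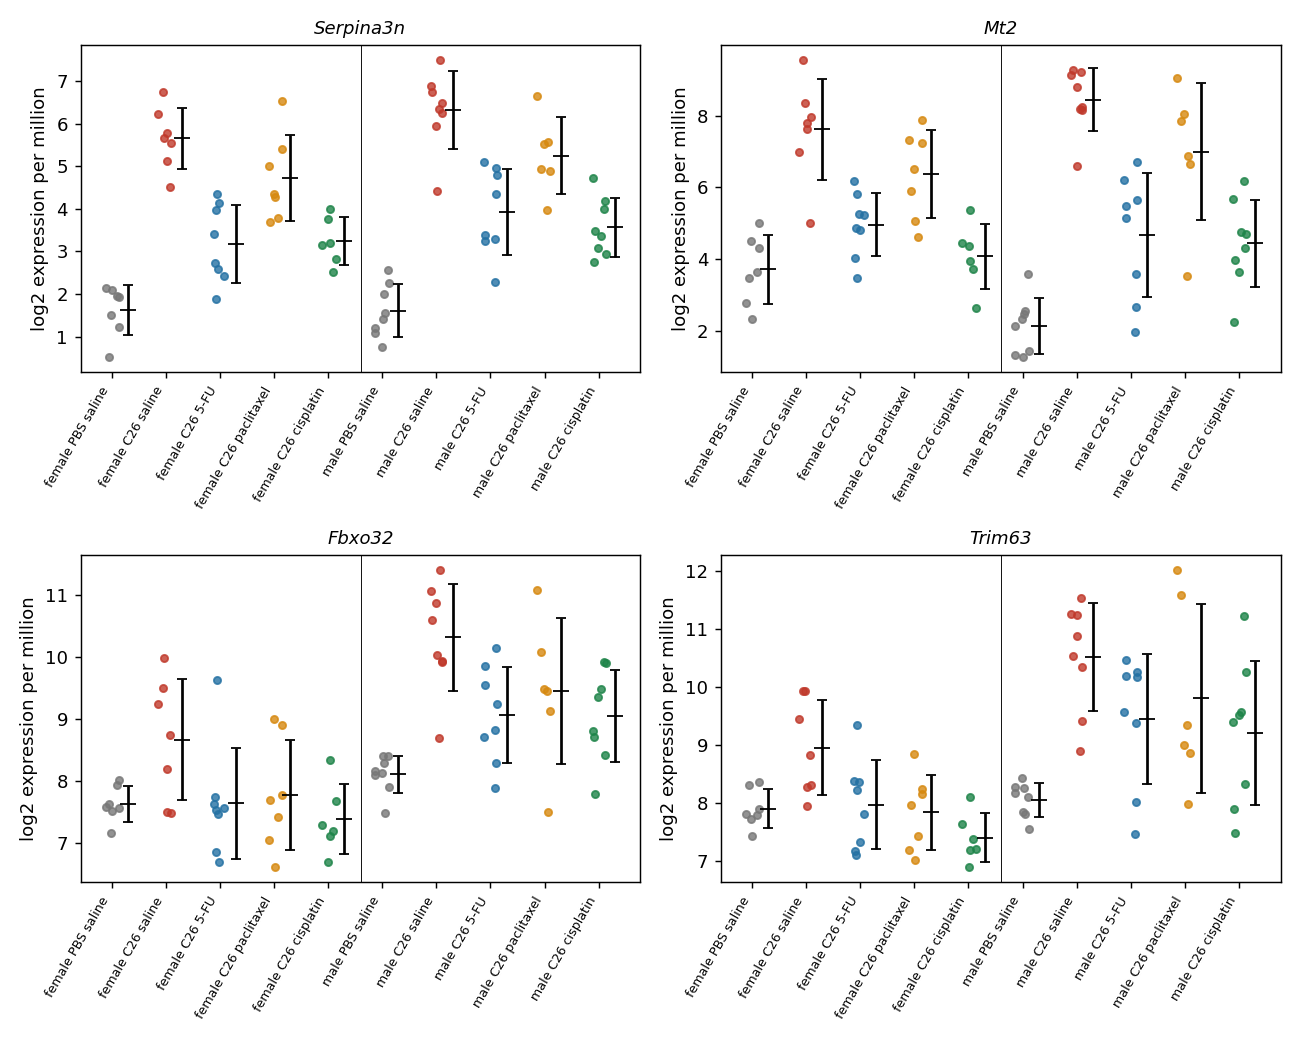
Log2 expression of Serpina3n, Mt2, Fbxo32 and Trim63 in each library by group, with the mean and SD of the group. Serpina3n stood at 1.62 ± 0.59 in female PBS and 5.66 ± 0.72 in female C26 saline muscle, and Fbxo32 at 8.11 ± 0.30 in male PBS and 10.32 ± 0.86 in male C26 saline muscle.

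5-Fluorouracil lowered inflammatory transcripts in tumour-bearing females (8 versus 7 C26 saline libraries). Serpina3n fell by 2.48 ± 0.41 (adjusted p = 0.000121), Socs3 by 3.01 ± 0.52 (adjusted p = 0.00027), Stat3 by 1.22 ± 0.20 (adjusted p = 0.000121) and Lbp by 1.92 ± 0.30 (adjusted p = 9.19e-05), each in 8 of 8 libraries. The chemokine Cxcl14 fell by 1.40 ± 0.21 and the TGF-beta receptor Tgfbr2 by 0.81 ± 0.15. Mt2 fell by 2.65 ± 0.62 (adjusted p = 0.0106), a call lost without C26 saline replicate 6 (-2.33, adjusted p = 0.0663). Fbxo32 (-1.03 ± 0.40, adjusted p = 0.248) and Trim63 (-0.99 ± 0.46, adjusted p = 0.423) did not pass, though Fbxo32 did with quality weights. Of the IL-6/STAT3 and acute-phase genes 0 of 31 rose and 17 fell (1 and 24 adjusted over the list alone, median -1.22, adjusted p = 2.67e-31, or 9.58e-05 with an estimated correlation). Of the neutrophil markers 0 of 10 rose and 6 fell (0 and 10 adjusted over the list alone, median -2.41, adjusted p = 5.68e-19, or 0.00342 with an estimated correlation), with the calgranulin S100a9 at -3.60 ± 0.68 and Csf3r at -2.63 ± 0.48, calls lost with the compared groups fitted alone. Of the macrophage markers 0 of 20 rose and 7 fell (0 and 16 adjusted over the list alone, median -0.90, adjusted p = 3.68e-21, or 0.0165 with an estimated correlation), with Fcgr3 at -1.10 ± 0.20. Of the NF-kB and inflammation genes 0 of 18 rose and 1 fell (0 and 5 adjusted over the list alone, median -0.28, adjusted p = 0.000245, or 0.0165 with an estimated correlation), with the cytokine Il1b at -2.96 ± 0.61, also lost in that fit.

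No ribosomal protein passed in treated females, and the list's median was -0.21 (adjusted p = 1.7e-09, or 0.641 with an estimated correlation). The FoxO and glucocorticoid targets had a median of -0.36 (adjusted p = 0.00038, or 0.667 with an estimated correlation). The fast fibre list, at 0.08 (adjusted p = 0.0236, or 0.667 with an estimated correlation), was not called with quantile normalization (adjusted p = 0.829) or without the libraries of high GC slope (adjusted p = 0.251). The pyrimidine and folate list, which holds the genes of the pathway the drug blocks, had no called member and a median of -0.04 (adjusted p = 0.837, or 0.87 with an estimated correlation). In all, 21 genes rose and 166 fell. The count of 187 became 108 with a mean log2 value of at least 1, 87 with the compared groups alone, 426 with the GC slope as a covariate and 987 with quality weights. It was 102 and 68 without C26 saline replicates 3 and 6, and 113, 101, 122 and 114 without 5-fluorouracil replicates 3, 4, 5 and 8.

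Paclitaxel in females (7 versus 7 libraries) called 0 genes by limma, with 845 at an unadjusted p under 0.05. The count was 1 with the compared groups alone, without C26 saline replicate 7 or without the libraries of high GC slope, and 118 with quality weights. Serpina3n lay at -0.94 ± 0.42 (adjusted p = 0.764), Socs3 at -1.41 ± 0.54 (adjusted p = 0.64), Mt2 at -1.25 ± 0.64 (adjusted p = 0.81) and Trim63 at -1.12 ± 0.47 (adjusted p = 0.7). Lists shifted by smaller amounts. The fatty acid oxidation genes, which burn lipid in mitochondria, had a median of -0.39 (adjusted p = 1.01e-13, or 0.18 with an estimated correlation), the IL-6/STAT3 genes of -0.40 (adjusted p = 7.96e-08, or 0.166 with an estimated correlation) and the ribosome biogenesis genes of -0.18 (adjusted p = 8.13e-08, or 0.149 with an estimated correlation). The antioxidant list had a median of -0.15 (adjusted p = 1.81e-06, or 0.0399 with an estimated correlation), with 4 members down adjusted over the list alone. The FoxO and glucocorticoid targets had a median of -0.43 (adjusted p = 1.04e-06, or 0.321 with an estimated correlation). The tubulins and microtubule proteins, which hold the drug's target, had a median of -0.01 (adjusted p = 0.911, or 0.951 with an estimated correlation) and a mean of 0.02. In simulated data of this comparison, 86.6% of genes changed 2-fold were recovered.

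Cisplatin in females (6 versus 7 libraries) lowered acute-phase genes. Mt2 fell by 3.53 ± 0.66 (adjusted p = 0.000969), Serpina3n by 2.41 ± 0.44 (adjusted p = 0.000753), Socs3 by 2.78 ± 0.56 (adjusted p = 0.00221) and Lbp by 1.99 ± 0.33 (adjusted p = 0.000441), each in 6 of 6 libraries. Chac1, a glutathione-degrading enzyme of the ATF4 response, fell by 2.41 ± 0.43, and the neutrophil chemokine receptor Cxcr2 by 4.12 ± 0.84. Tfrc rose by 2.93 ± 0.59 (adjusted p = 0.00212), and Ephx1, an epoxide hydrolase of detoxification, by 0.85 ± 0.15 (adjusted p = 0.000545), in 6 of 6 libraries. Fbxo32 (-1.28 ± 0.43, adjusted p = 0.101) and Trim63 (-1.55 ± 0.49, adjusted p = 0.081) did not pass. Both passed with quality weights and without the libraries of high GC slope, and Trim63 also with the compared groups alone.

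By list, of the IL-6/STAT3 and acute-phase genes 0 of 31 rose and 15 fell (1 and 23 adjusted over the list alone, median -1.30, adjusted p = 4.04e-20, or 0.00407 with an estimated correlation), and of the neutrophil markers 0 of 10 rose and 2 fell (0 and 8 adjusted over the list alone, median -1.72, adjusted p = 7.02e-09, or 0.0853 with an estimated correlation). Of the ribosome biogenesis genes 0 of 29 rose and 3 fell (0 and 14 adjusted over the list alone, median -0.24, adjusted p = 3.1e-07, or 0.0853 with an estimated correlation), with Myc, a driver of ribosome production, at -1.15 ± 0.25. Of the antioxidant genes 0 of 23 rose and 4 fell (0 and 8 adjusted over the list alone, median -0.36, adjusted p = 6.56e-05, or 0.07 with an estimated correlation), with Gpx3 at -1.25 ± 0.22. Of the metal and iron handling genes 1 rose and 2 fell (1 and 4 adjusted over the list alone), with a median of -0.06 (adjusted p = 0.223, or 0.0345 with the GC slope as a covariate, and not called with an estimated correlation).  The ribosomal protein and FoxO lists had medians of -0.33 (adjusted p = 1.56e-10, or 0.55 with an estimated correlation) and -0.53 (adjusted p = 0.000146, not called with an estimated correlation). Mitochondrially encoded genes had a median of 0.68 (adjusted p = 0.00223, not called with an estimated correlation), which was 0.08 with the GC slope as a covariate (adjusted p = 0.428). The mean GC slope was -0.15 ± 0.06 in cisplatin and 0.01 ± 0.21 in C26 saline females. In all, 48 genes rose and 182 fell. The count of 230 became 428 with the GC slope as a covariate, 668 with the compared groups alone, 906 without the libraries of high slope and 2325 with quality weights. It was 150, 142 and 74 without C26 saline replicates 1, 3 and 6, and 110, 92, 99 and 124 without cisplatin replicates 1, 3, 5 and 6.

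In males 5-fluorouracil (8 versus 8 libraries) lowered acute-phase genes and raised single genes of fast fibres and the neuromuscular junction. Mt2 fell by 3.77 ± 0.59 (adjusted p = 8.43e-06), Lcn2 by 3.74 ± 0.60 (adjusted p = 9.94e-06) and Serpina3n by 2.40 ± 0.40 (adjusted p = 1.39e-05), each in 8 of 8 libraries. Fbxo32 fell by 1.26 ± 0.38 (adjusted p = 0.0134). Trim63 lay at -1.07 ± 0.44 (adjusted p = 0.066) and passed with the GC slope as a covariate (adjusted p = 0.0332), with quantile normalization, with quality weights, without the libraries of high slope, and without C26 saline replicate 2 (-1.23) or 8 (-1.30) or 5-fluorouracil replicate 2 (-1.18). The myosin-binding protein Mybph rose by 3.32 ± 0.50 (adjusted p = 4.43e-06), Nmrk2 by 2.80 ± 0.46 and Dusp29 by 2.96 ± 0.41. Casq1 rose by 1.65 ± 0.24, acetylcholinesterase (Ache) by 1.32 ± 0.21 and its collagen tail Colq by 1.11 ± 0.18.

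Of the 17 lists called in these males, 0 were called with an estimated correlation. Of the proteasome subunits 0 of 32 rose and 19 fell (0 and 20 adjusted over the list alone, median -0.45, adjusted p = 9.71e-10, or 0.188 with an estimated correlation), with Psmc2 at -0.61 ± 0.10. Of the IL-6/STAT3 genes 0 of 31 rose and 20 fell (0 and 22 adjusted over the list alone, median -1.0, adjusted p = 8.45e-10, or 0.188 with an estimated correlation), and of the neutrophil markers 0 of 10 rose and 10 fell (0 and 10 adjusted over the list alone, median -2.33, adjusted p = 4.23e-07, or 0.188 with an estimated correlation). Of the unfolded protein response genes 0 of 20 rose and 13 fell (0 and 15 adjusted over the list alone, median -0.36, adjusted p = 2.53e-06, or 0.188 with an estimated correlation), with Xbp1 at -0.74 ± 0.12. Of the nuclear oxidative phosphorylation genes 37 of 77 rose and 0 fell (52 and 0 adjusted over the list alone, median 0.44, adjusted p = 1.03e-11, or 0.45 with an estimated correlation), with the complex III subunit Uqcrc1 at 0.60 ± 0.17. Of the fast fibre genes 8 of 18 rose and 0 fell (14 and 0 adjusted over the list alone, median 0.52, adjusted p = 1.25e-07, or 0.275 with an estimated correlation), with the tropomyosin Tpm1 at 0.89 ± 0.16. With the GC slope as a covariate these 2 medians were 0.21 (adjusted p = 2.17e-08) and 0.22 (adjusted p = 5.76e-05). Of the denervation and neuromuscular junction genes 10 of 22 rose and 2 fell (10 and 3 adjusted over the list alone, median 0.18, adjusted p = 0.0121, or 0.318 with an estimated correlation), with the adult acetylcholine receptor subunit Chrne at 1.18 ± 0.19, and this call was lost without the libraries of high slope (adjusted p = 0.101).

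Ribosomal proteins in the same males had a median of 0.01 (adjusted p = 0.954, or 0.992 with an estimated correlation), which became -0.17 with the GC slope as a covariate (adjusted p = 8.63e-06). Mitochondrially encoded genes had a median of -0.56 (adjusted p = 0.245, or 0.889 with an estimated correlation), which became 0.45 (adjusted p = 0.000177). They passed as lower with quantile normalization (adjusted p = 0.0359). The mean GC slope was 0.12 ± 0.26 in these 8 libraries and -0.11 ± 0.06 in C26 saline. The p53 target and pyrimidine lists had medians of -0.19 (adjusted p = 0.192, or 0.32 with an estimated correlation) and 0.16 (adjusted p = 0.308, or 0.521 with an estimated correlation), and the p53 target Eda2r, a receptor of the tumour necrosis factor family, fell by 1.70 ± 0.32. In all, 1564 genes rose and 1669 fell. The count of 3233 was 2007 without 5-fluorouracil replicate 4, and 1907 of these genes were called with the GC slope as a covariate.

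In males paclitaxel (6 versus 8 libraries) lowered single genes of the proteasome and of endoplasmic reticulum stress. The potassium channel Kcnh2 rose by 2.06 ± 0.33 (adjusted p = 0.000349) in 6 of 6 libraries, Dusp29 by 2.33 ± 0.44 in 6 of 6 and Mybph by 2.47 ± 0.54 in 5 of 6. Lcn2 fell by 2.37 ± 0.65 (adjusted p = 0.00594) in 6 of 6, the endoplasmic reticulum stress factor Manf by 0.86 ± 0.17 in 6 of 6, cathepsin L by 1.13 ± 0.25 in 5 of 6, and the proteasome subunits Psmb1 and Psmc2 by 0.55 ± 0.10 and 0.57 ± 0.11 in 6 and 5. These calls held in every setting tried. Serpina3n fell by 1.07 ± 0.43 (adjusted p = 0.0469), but the call was lost with the GC slope as a covariate (-1.08, adjusted p = 0.171), with the compared groups alone, with quality weights, and without any 1 of C26 saline replicates 1, 2, 5, 6, 7 and 8 (-0.90 to -1.08) or paclitaxel replicates 1, 2, 4, 5 and 6 (-0.81 to -1.13). Trim63 did not pass, at -0.71 ± 0.48 (adjusted p = 0.245).

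In all, 1864 genes rose and 2560 fell in this comparison. With the GC slope as a covariate the 4424 calls became 497, of which 302 were shared, and without the libraries of high slope they became 722, of which 493 were shared. The latter fit left out 4 of 6 paclitaxel and 0 of 8 C26 saline libraries, so it also had fewer samples. The count was 2575 and 2356 without paclitaxel replicates 1 and 5. By list, of the proteasome subunits 0 of 32 rose and 20 fell (0 and 21 adjusted over the list alone, median -0.44, adjusted p = 1.42e-07, or 0.797 with an estimated correlation), and the median was -0.35 with the GC slope as a covariate. Of the unfolded protein response genes 0 of 20 rose and 13 fell (0 and 14 adjusted over the list alone, median -0.39, adjusted p = 0.000202, or 0.797 with an estimated correlation), and of the heat shock genes 0 of 22 rose and 9 fell (0 and 9 adjusted over the list alone, median -0.42, adjusted p = 0.0065, or 0.797 with an estimated correlation). Of the nuclear oxidative phosphorylation genes 26 of 77 rose and 3 fell (32 and 5 adjusted over the list alone, median 0.41, adjusted p = 1.61e-05, or 0.854 with an estimated correlation), where the median became 0.03 with the covariate (adjusted p = 0.299). Of the fast fibre genes 10 of 18 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.51, adjusted p = 0.000178, or 0.797 with an estimated correlation), where it became 0.07 (adjusted p = 0.0436) and the call was lost with quantile normalization (adjusted p = 0.052). Of the glycolysis genes 11 of 28 rose and 3 fell (12 and 3 adjusted over the list alone, median 0.34, adjusted p = 0.00471, or 0.797 with an estimated correlation), a call also lost with quantile normalization (adjusted p = 0.0584). Of the mitochondrially encoded genes 0 of 13 rose and 6 fell (0 and 9 adjusted over the list alone, median -1.18, adjusted p = 0.0065, or 0.854 with an estimated correlation), and the median turned to 0.36 with the covariate (adjusted p = 3.25e-05). Their share of expression averaged 5.24 ± 4.90% (SD) in paclitaxel and 9.37 ± 3.73% in C26 saline males.

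Other lists passed in this comparison only in other settings. The IL-6/STAT3 genes had a median of -0.42 (adjusted p = 0.0782, or 0.854 with an estimated correlation), with an adjusted p of 3.25e-05 under the covariate and 0.0347 with quantile normalization. The ribosomal proteins had a median of 0.13 (adjusted p = 0.855, or 0.994 with an estimated correlation), which became -0.27 with the covariate (adjusted p = 4.79e-18). The tubulins and microtubule proteins had a median of 0.13 (adjusted p = 0.689, or 0.99 with an estimated correlation), which became -0.15 (adjusted p = 0.0312).

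Cisplatin in males (8 versus 8 libraries) lowered acute-phase genes and raised single genes of fast fibres. Mt2 fell by 4.00 ± 0.59 (adjusted p = 3.53e-06), Lcn2 by 3.81 ± 0.60 (adjusted p = 6.28e-06), Serpina3n by 2.76 ± 0.40 (adjusted p = 2.37e-06) and Slc39a14 by 2.03 ± 0.26, each in 8 of 8 libraries. Ephx1 rose by 1.02 ± 0.13 (adjusted p = 5.69e-07) in 8 of 8, Mybph by 3.25 ± 0.50, Dusp29 by 2.94 ± 0.41, Casq1 by 1.68 ± 0.24 and Ache by 1.29 ± 0.21. Fbxo32 fell by 1.27 ± 0.38 (adjusted p = 0.0153) in 8 of 8 libraries and Trim63 by 1.30 ± 0.44 (adjusted p = 0.0325) in 7 of 8. The call of Fbxo32 was lost without C26 saline replicate 5 (-1.11). That of Trim63 was lost without C26 saline replicate 1, 3, 5 or 6 or cisplatin replicate 1, 2 or 8, at -1.06 to -1.30, and with the compared groups alone.

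By list, of the proteasome subunits 0 of 32 rose and 24 fell (0 and 28 adjusted over the list alone, median -0.48, adjusted p = 2.18e-16, or 0.0645 with an estimated correlation), with Psmc2 at -0.70 ± 0.10. Of the IL-6/STAT3 genes 0 of 31 rose and 24 fell (0 and 25 adjusted over the list alone, median -1.24, adjusted p = 7.41e-16, or 0.0218 with an estimated correlation), and of the neutrophil markers 0 of 10 rose and 10 fell (0 and 10 adjusted over the list alone, median -2.30, adjusted p = 2.44e-07, or 0.14 with an estimated correlation). Of the unfolded protein response genes 0 of 20 rose and 10 fell (0 and 15 adjusted over the list alone, median -0.47, adjusted p = 2.26e-07, or 0.14 with an estimated correlation). Of the heat shock genes 0 of 22 rose and 7 fell (0 and 9 adjusted over the list alone, median -0.47, adjusted p = 4.76e-05, or 0.274 with an estimated correlation), with the chaperone Hsp90ab1 at -0.53 ± 0.10. Of the antioxidant genes 2 of 23 rose and 11 fell (2 and 14 adjusted over the list alone, median -0.48, adjusted p = 5.09e-05, or 0.0645 with an estimated correlation), with thioredoxin (Txn1) at -0.80 ± 0.13. Of the fast fibre genes 7 of 18 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.31, adjusted p = 1.23e-06, or 0.237 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.0794). Of the ATF4 and amino acid response genes 1 of 29 rose and 9 fell (2 and 10 adjusted over the list alone, median -0.21, adjusted p = 0.0303, or 0.471 with an estimated correlation), with asparagine synthetase (Asns) at -1.01 ± 0.22.

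Autophagy genes in these males had a median of -0.21 (adjusted p = 4.76e-05, or 0.19 with an estimated correlation). Nuclear oxidative phosphorylation genes had 1 called member and a median of 0.19 (adjusted p = 5.97e-05, or 0.658 with an estimated correlation). In all, 1062 genes rose and 1141 fell. The count of 2203 became 1028 with the compared groups alone, 3968 with the GC slope as a covariate and 3407 without the libraries of high slope.

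**Figure D3:**
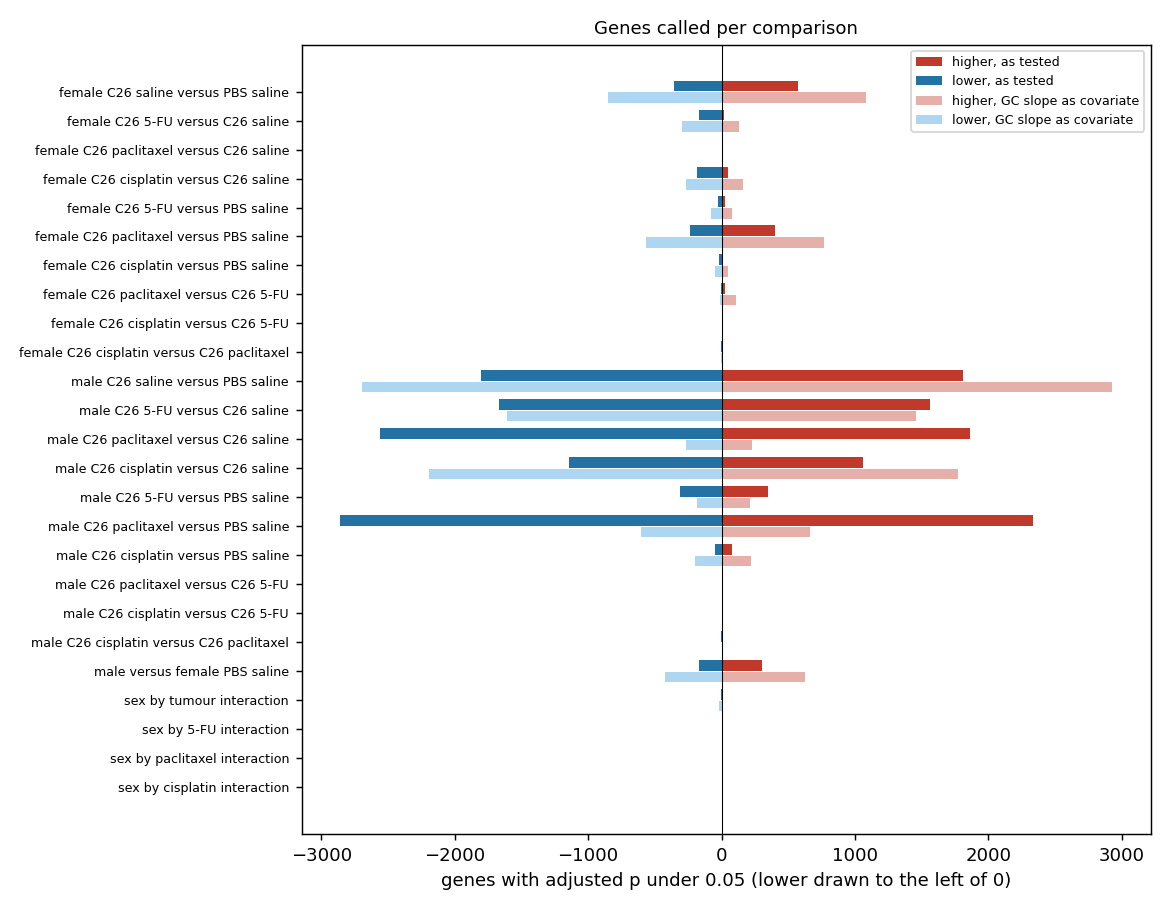
Number of genes called up and down in each comparison, as tested and with the GC slope as a covariate. Male paclitaxel against C26 saline falls from 4424 to 497 called genes, while male C26 saline against PBS rises from 3617 to 5624.

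**Figure D4:**
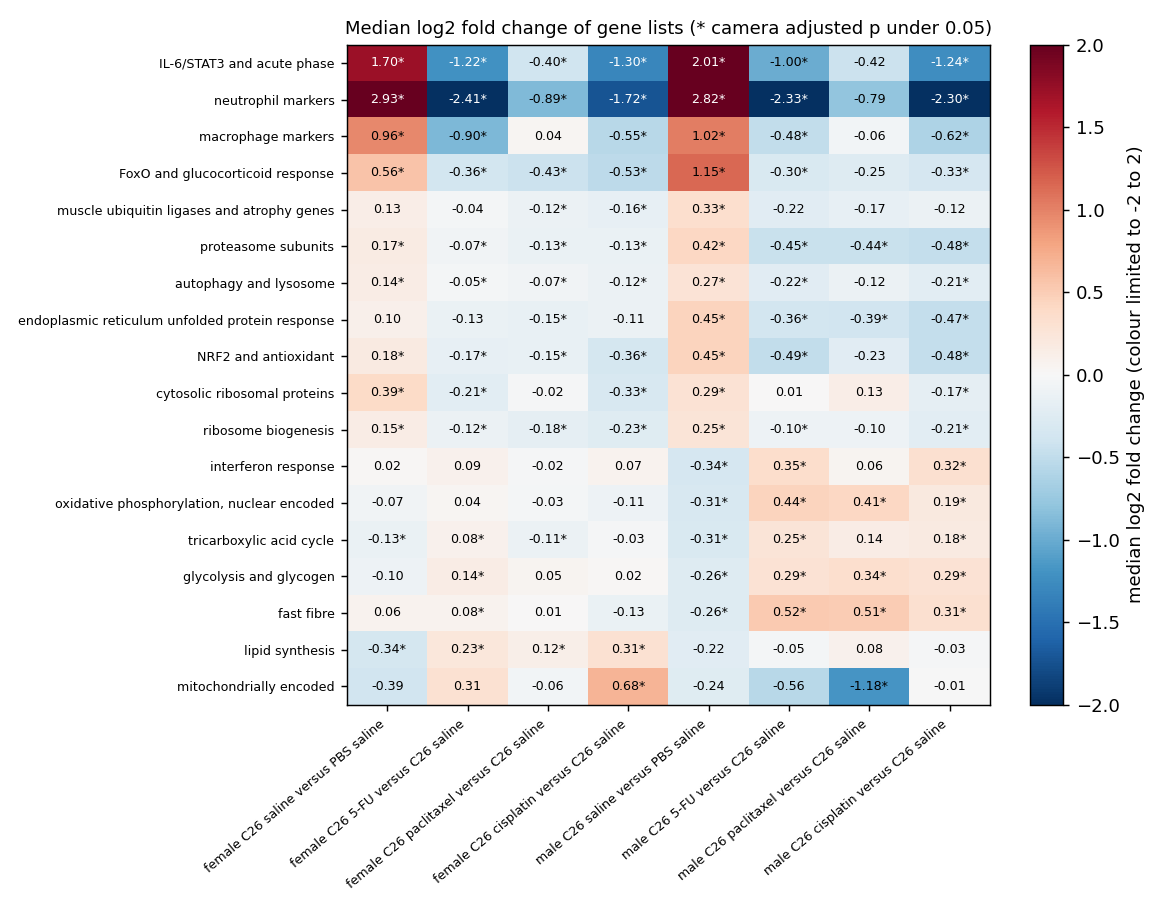
Median log2 change of 18 gene lists in the 8 main comparisons, with colour limited to -2 and 2 and an asterisk where camera's adjusted p was under 0.05. The IL-6/STAT3 list is at 1.70 and 2.01 under the tumour in females and males and at -1.22, -0.40 and -1.30 under 5-fluorouracil, paclitaxel and cisplatin in females.

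The drug effects were set against the tumour effect, gene by gene. Both use the C26 saline libraries, so these were divided at random between the effects in 100 draws. The correlation across genes was then -0.439 ± 0.0580 (SD over draws) for 5-fluorouracil, -0.145 ± 0.0990 for paclitaxel and -0.447 ± 0.0806 for cisplatin in females, and -0.548 ± 0.0464, -0.299 ± 0.0475 and -0.628 ± 0.0395 in males. With all libraries it was -0.768, -0.445 and -0.721 in females, where unchanged groups gave -0.522, -0.496 and -0.479 in simulation, and -0.709, -0.422 and -0.817 in males, where they gave -0.496, -0.448 and -0.502. The simulated range of the correlation in draws (95% of simulations) was -0.443 to 0.389, -0.414 to 0.430 and -0.388 to 0.385 in females and -0.262 to 0.296, -0.357 to 0.324 and -0.312 to 0.310 in males. The correlations of female 5-fluorouracil and of paclitaxel in both sexes lay within it.

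Drug effects were also set against each other between the sexes. Across genes they correlated at r = 0.363 (rho = 0.293, jackknife SE 0.274) for 5-fluorouracil, 0.214 (rho = 0.301, SE 0.449) for paclitaxel and 0.349 (rho = 0.268, SE 0.223) for cisplatin. With the GC slope as a covariate r was 0.561, 0.298 and 0.547, and without the libraries of high slope 0.380, 0.216 and 0.57. Under 5-fluorouracil 17 genes rose and 105 fell in both sexes, where independent lists would share 2.37 and 20, and under cisplatin 20 rose and 118 fell, against 3.68 and 15. limma called 0 genes for each drug's interaction with sex, with 2044, 2704 and 1993 genes at an unadjusted p under 0.05 for 5-fluorouracil, paclitaxel and cisplatin. With quality weights the counts were 456, 3714 and 355. The smallest adjusted p in each was that of the acute-phase protein Orm1 under 5-fluorouracil (-3.42 ± 0.72, adjusted p = 0.145), the repair enzyme Mgmt under paclitaxel (1.13 ± 0.27, adjusted p = 0.226) and Aifm3 under cisplatin (2.87 ± 0.62, adjusted p = 0.0649). Aifm3 passed with quantile normalization (adjusted p = 0.0424). The cisplatin count was 9 in that setting, 4 and 2 without female C26 saline replicate 6 and female cisplatin replicate 1, and 144 without male C26 saline replicate 4. The 5-fluorouracil count was 1 without female C26 saline replicate 2 or male C26 saline replicate 4.

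Treated mice were also compared with PBS mice of the same sex. In females 53 genes differed after 5-fluorouracil, 635 after paclitaxel and 29 after cisplatin. Fkbp5 stayed above PBS by 2.06 ± 0.32 after 5-fluorouracil and 2.37 ± 0.34 after paclitaxel, and Bcl6b below it at -1.91 ± 0.31 after 5-fluorouracil and -2.35 ± 0.33 after cisplatin. Serpina3n was higher by 3.10 ± 0.42 after paclitaxel, and Ackr1, the venular chemokine receptor, by 2.02 ± 0.23 (adjusted p = 1.03e-08). The doppel gene Prnd was lower after cisplatin (-4.09 ± 0.72). These genes differed in every treated library. With the GC slope as a covariate the counts were 156, 1332 and 97, and with quality weights 390, 1907 and 868. With the compared groups alone the count was 86 after 5-fluorouracil and 185 after cisplatin. The 5-fluorouracil count was 34, 35 and 24 without PBS replicates 1, 3 and 5 and 28 and 31 without 5-fluorouracil replicates 1 and 3. The paclitaxel count was 423 and 406 without paclitaxel replicates 2 and 7, and the cisplatin count 19 and 18 without PBS replicates 5 and 6 and 15 without cisplatin replicate 3 or 6.

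In males 659 genes differed from PBS after 5-fluorouracil, 5192 after paclitaxel and 125 after cisplatin. Without the libraries of high GC slope the counts were 34, 10 and 54, and with the slope as a covariate 396, 1272 and 422. After 5-fluorouracil and cisplatin they were 3292 and 312 with quality weights and 332 and 67 with the compared groups alone. Prnd was lower after 5-fluorouracil (-5.18 ± 0.65, adjusted p = 3.24e-07) and the stem cell factor receptor Kit at -1.41 ± 0.24. The endothelial diaphragm protein Plvap was higher by 1.89 ± 0.22 after paclitaxel (adjusted p = 1.94e-08). After cisplatin Fkbp5 was higher (1.93 ± 0.31) and the heat shock cochaperone Dnajb1 lower (-1.80 ± 0.28). Each held in all treated libraries. Left-out libraries moved the 5-fluorouracil count to 345, 403, 417, 315 and 357 (PBS replicates 1, 3, 5, 6 and 7) and to 1527, 1222, 237, 192 and 317 (5-fluorouracil replicates 1, 3, 4, 7 and 8). They moved the cisplatin count to 65, 79, 76 and 61 (PBS replicates 1, 2, 5 and 6) and to 251, 34 and 82 (cisplatin replicates 2, 4 and 7).

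Between drugs in females, the chemokine Cxcl14 was higher after paclitaxel than after 5-fluorouracil (1.29 ± 0.21, adjusted p = 0.000548), and so was the lysosomal macrophage protein Cd68 (1.40 ± 0.24, adjusted p = 0.000951), a call lost with the compared groups fitted alone. In all, 26 genes differed there, 1 with the compared groups alone, 17 with a mean log2 value of at least 1, 57 with a replicate block, 117 with the GC slope as a covariate and 393 with quality weights. The count was 73, 9, 10, 10 and 14 without 5-fluorouracil replicates 2, 3, 4, 5 and 8, and 56, 7, 7, 79, 10, 74 and 12 without paclitaxel replicates 1 to 7. Against paclitaxel, cisplatin raised Ephx1 (0.95 ± 0.15, adjusted p = 0.00021) and lowered Cxcl14 (-1.19 ± 0.22) and Ecscr (-0.84 ± 0.16, adjusted p = 0.00748 for each). Cxcl14 was lost without cisplatin replicate 5 (-1.08) and Ecscr without the libraries of high GC slope. The count of 3 was 5 without paclitaxel replicate 1 or cisplatin replicate 2, 41 without paclitaxel replicate 4, 7 with the compared groups alone and 728 with quality weights.

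Between drugs in males, paclitaxel exceeded 5-fluorouracil for the transcription factor Osr2 (1.65 ± 0.34, adjusted p = 0.0496). The count of 2 was 4 with a replicate block and 0 with quality weights. It was 14 without paclitaxel replicate 4, 1 without paclitaxel replicate 2 or 6 or 5-fluorouracil replicate 7, and 0 without any other library except 5-fluorouracil replicate 5. Cisplatin lay below paclitaxel for the peptidoglycan-binding protein Pglyrp1 (-2.26 ± 0.43, adjusted p = 0.0232) and the bile acid enzyme Hsd3b7 (-0.74 ± 0.15, adjusted p = 0.0264). That count of 2 was 4339 with quality weights and 607 with a replicate block. It was 2852 and 2592 without paclitaxel replicates 4 and 6, 0 without paclitaxel replicates 1, 2, 3 or 5 or cisplatin replicates 1 or 3, and 4143, 1, 96, 1 and 5 without cisplatin replicates 4 to 8. No male call between drugs held with the GC slope as a covariate. Cisplatin and 5-fluorouracil differed in 0 genes in either sex by limma, with 465 genes in females and 574 in males at an unadjusted p under 0.05, and with 2 female genes called under quality weights.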

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

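The alternatives that use the GC slope, and its limit of 0.1, were chosen only after the slopes had been seen. The bounds for each weighing were set before its own result was computed.

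The search for a library far from its group covered 18 measures in 10 groups, 180 in all, and found 11. Chance finds a library apart in about 1 in 20 groups. Fbxo32 stood at 9.638 (log2) in female 5-fluorouracil replicate 1, where the other libraries lay at 6.681 to 7.744, and Cdkn1a at 4.432 in female PBS replicate 1 (others 5.341 to 5.972). Foxo1 was at 6.390 in female PBS replicate 4 (others 4.208 to 4.955), and the pyruvate dehydrogenase kinase Pdk4 at 8.550 in female cisplatin replicate 2 (others 10.164 to 10.746). Mt2 was at 6.596 in male C26 saline replicate 4 (others 8.146 to 9.256), and Socs3 at 3.603 in male PBS replicate 7 (others 0.894 to 1.739). The growth factor Igf1 was at -0.481 in male cisplatin replicate 4 (others 2.084 to 3.749), the collagen Col1a1 at 9.922 in male 5-fluorouracil replicate 5 (others 4.914 to 7.122), and the stress gene Gadd45a at 6.624 in female C26 saline replicate 6 (others 5.140 to 5.405). The GC slope was 0.452 in female C26 saline replicate 7 (others -0.129 to 0.064), and the mitochondrial share 17.720% in male C26 saline replicate 7 (others 6.528 to 10.748%).

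The tumour effect differed between the sexes by the interaction test for 5 genes. Nr4a2 had an interaction of 2.534 (female effect -2.112, male effect 0.422), and Htra4 of -2.759 (1.192 and -1.567). Orm1 had 3.831 (-1.454 and 2.377), a call lost without the libraries of high GC slope, where 3 of the 5 held. The muscle methyltransferase Mettl21c had -2.495 (-0.358 and -2.852), lost with a mean log2 value of at least 1 and without male C26 saline replicate 1 (-2.36) or 6 (-2.34). The carbonyl reductase Cbr2 had -1.699 (0.295 and -1.404) and lost its call in 23 of the fits that left out a library.

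The female library with conflicting labels was compared with the female PBS libraries. It lay above their range for Mstn (5.987; range 4.384 to 5.959), Foxo1 (6.494; 4.208 to 6.390), Mt2 (5.644; 2.325 to 4.996), Ppargc1a (5.622; 3.811 to 4.757), Socs3 (3.873; 0.611 to 2.234), Igf1 (3.641; 1.164 to 3.462) and Serpina3n (4.624; 0.520 to 2.132). For Serpina3n and Socs3 it lay within the female C26 saline libraries (4.520 to 6.738 and 2.549 to 7.736) and above the 5-fluorouracil libraries (1.874 to 4.342 and 0.671 to 2.601). Trim63 (7.455), Gadd45a (4.492) and Pdk4 (10.133) lay below the C26 saline libraries (from 7.951, 5.140 and 10.166) and within the range of the 5-fluorouracil libraries (7.099 to 9.346, 4.102 to 5.466 and 9.684 to 11.950).

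Many genes were called between male paclitaxel and male C26 saline, 4424 in all. Depth as the cause was excluded, since with log2 depth as a covariate the called genes kept a slope of 0.997 of their changes and 4454 genes were called. With the GC slope as a covariate the called genes kept 0.3289 of their changes, between the bounds of 0.2 and 0.8, so a GC bias of the libraries and the drug cannot be told apart for these genes. What keeps it open is that 4 of 6 paclitaxel and 0 of 8 C26 saline libraries had a slope above 0.1. The drug's own effect on these genes stays open as well.

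Drug effects correlated negatively with the tumour effect. Under the draws that shared no C26 saline library, the covariance lay below the 2.5th percentile of simulated unchanged groups in 5 of 6 comparisons (-0.103, -0.122, -0.202, -0.120 and -0.220), and the exception was female paclitaxel (-0.0279 against -0.0748). For female paclitaxel an opposite effect is thus not shown without the GC covariate, and the correlation of female 5-fluorouracil (-0.4393, simulated from -0.4426) and male paclitaxel (-0.2988, from -0.3566) also lay within its simulated range, which left 3 of 6 beyond it. With the GC slope as a covariate the covariance lay below 0 and the simulation in 6 of 6 (female paclitaxel -0.0408 against -0.0214), which excludes the GC bias as the whole cause. A smaller tumour in treated mice may underlie the reversal, but tumour size was not analysed here.

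More genes were called for the tumour in males than in females, 3617 against 928. Libraries of high GC slope as the cause were excluded, since without them the ratio was 3.053 (5049 against 1654). The median residual SD was 1.084 times as large in females (0.329 against 0.304), between the bounds set for it. The fit gives both sexes 1 spread per gene, so this difference could not lower the female count through its standard errors, and with the compared groups alone 580 genes rose in females and 2100 in males. A sex difference in the response is a biological explanation, and the interaction test called 5 genes.

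In 100 splits of the same libraries (for interactions, of the sexes within each treatment), chance was excluded for the tumour effect in females (1 split as large, the real one; real 928, highest other 394) and males (1; 3617 and 1130). The same held for 5-fluorouracil against C26 saline in females (1; 187 and 177) and males (1; 3233 and 513), for cisplatin in females (1; 230 and 78) and males (1; 2203 and 1305), and for paclitaxel in males (1; 4424 and 3652). Against PBS, chance was excluded for 5-fluorouracil (1; 53 and 1), paclitaxel (1; 635 and 190) and cisplatin (1; 29 and 3) in females, and for 5-fluorouracil (1; 659 and 49), paclitaxel (2; 5192 and 5405) and cisplatin (1; 125 and 47) in males. It was also excluded for female paclitaxel against 5-fluorouracil (2; 26 and 945), female cisplatin against paclitaxel (1; 3 and 1), the sexes under PBS (1; 470 and 14) and the interaction of sex and tumour (2; 5 and 42). Chance was not excluded for male paclitaxel against 5-fluorouracil (12; 2 and 958) and male cisplatin against paclitaxel (23; 2 and 5639). The real count was 0, so that the splits decide nothing, for female paclitaxel against C26 saline (100; 0 and 1), cisplatin against 5-fluorouracil in females (100; 0 and 2) and males (100; 0 and 3671) and the interactions of sex with 5-fluorouracil (100; 0 and 438), paclitaxel (100; 0 and 463) and cisplatin (100; 0 and 565). Some splits called several times the real count, and what drove them was not tested. The median count of the other splits was 0.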

How the results depend on the processing

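The 2 alternatives that use the GC slope were chosen only after the slopes had been seen, and the others were planned. Where a setting below changed a value, the cause was not tested. A drug without another group named stands for its comparison with C26 saline, and tumour for C26 saline, set against PBS unless a library is named. Counts not given below lay within 1.5 times the reported ones.

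Leaving out 1 library at a time gave these counts of called genes, after the count with all libraries and with the number of the replicate left out. Female tumour 928 (538 without tumour 6 to 1062 without tumour 4). Female 5-fluorouracil 187 (68 without tumour 6 to 234 without 5-fluorouracil 1). Female paclitaxel 0 (0 to 1 without tumour 7). Female cisplatin 230 (74 without tumour 6 to 306 without tumour 4). Female 5-fluorouracil against PBS 53 (24 without PBS 5 to 64 without 5-fluorouracil 7). Female paclitaxel against PBS 635 (406 without paclitaxel 7 to 722 without paclitaxel 6). Female cisplatin against PBS 29 (15 without cisplatin 3 to 34 without PBS 4). Female paclitaxel against 5-fluorouracil 26 (7 without paclitaxel 2 to 79 without paclitaxel 4). Female cisplatin against 5-fluorouracil 0 (0 to 0). Female cisplatin against paclitaxel 3 (2 without cisplatin 5 to 41 without paclitaxel 4). Male tumour 3617 (3047 without tumour 5 to 3861 without tumour 4). Male 5-fluorouracil 3233 (2007 without 5-fluorouracil 4 to 3897 without tumour 4). Male paclitaxel 4424 (2356 without paclitaxel 5 to 5466 without paclitaxel 6). Male cisplatin 2203 (1481 without tumour 5 to 2687 without tumour 4). Male 5-fluorouracil against PBS 659 (192 without 5-fluorouracil 7 to 1527 without 5-fluorouracil 1). Male paclitaxel against PBS 5192 (3475 without paclitaxel 1 to 6252 without paclitaxel 4). Male cisplatin against PBS 125 (34 without cisplatin 4 to 251 without cisplatin 2). Male paclitaxel against 5-fluorouracil 2 (0 to 14 without paclitaxel 4). Male cisplatin against 5-fluorouracil 0 (0 to 0). Male cisplatin against paclitaxel 2 (0 to 4143 without cisplatin 4). Male against female PBS 470 (336 without female PBS 2 to 483 without female PBS 1). The tumour interaction 5 (3 without male tumour 1 to 102 without male tumour 4). The 5-fluorouracil interaction 0 (0 to 1 without female tumour 2). The paclitaxel interaction 0 (0 to 0). The cisplatin interaction 0 (0 to 144 without male tumour 4).

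With quality weights the counts of called genes were 2047 in female tumour, 987 in female 5-fluorouracil, 118 in female paclitaxel, 2325 in female cisplatin, 390 in female 5-fluorouracil against PBS, 1907 in female paclitaxel against PBS, 868 in female cisplatin against PBS, 393 in female paclitaxel against 5-fluorouracil, 2 in female cisplatin against 5-fluorouracil, 728 in female cisplatin against paclitaxel, 3292 in male 5-fluorouracil against PBS, 312 in male cisplatin against PBS, 0 in male paclitaxel against 5-fluorouracil, 4339 in male cisplatin against paclitaxel, 1722 in male against female PBS, 255 in the tumour interaction, 456 in the 5-fluorouracil interaction, 3714 in the paclitaxel interaction and 355 in the cisplatin interaction.

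With the compared groups fitted alone they were 87 in female 5-fluorouracil, 1 in female paclitaxel, 668 in female cisplatin, 86 in female 5-fluorouracil against PBS, 185 in female cisplatin against PBS, 1 in female paclitaxel against 5-fluorouracil, 7 in female cisplatin against paclitaxel, 1028 in male cisplatin, 332 in male 5-fluorouracil against PBS, 67 in male cisplatin against PBS, 0 in male paclitaxel against 5-fluorouracil, 0 in male cisplatin against paclitaxel, 876 in male against female PBS and 10 in the tumour interaction. With a mean log2 value of at least 1, which tests fewer genes, they were 108 in female 5-fluorouracil, 17 in female paclitaxel against 5-fluorouracil, 0 in male paclitaxel against 5-fluorouracil, 1 in male cisplatin against paclitaxel and 0 in the tumour interaction, and the correlation of drug and tumour effects in the draws was -0.608 for male 5-fluorouracil (-0.548 over all genes) and -0.718 for male cisplatin (-0.628). With quantile normalization they were 1 in male paclitaxel against 5-fluorouracil, 0 in male cisplatin against paclitaxel and 9 in the cisplatin interaction, and the fast fibre list of female 5-fluorouracil changed direction (adjusted p = 0.829, and 0.0236 before). With replicate numbers as a block they were 57 in female paclitaxel against 5-fluorouracil, 4 in male paclitaxel against 5-fluorouracil and 607 in male cisplatin against paclitaxel. No comparison had every pair correlated over 0.1 (female paclitaxel 0.0862 to 0.564 with 5 of 7 over, female paclitaxel against 5-fluorouracil 6 of 7, lowest -0.316). Yet 4 of 7 libraries were closest to their own number in female paclitaxel and 5-fluorouracil (0 to 3 elsewhere), so pairing stays open.

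Counts with the GC slope as a covariate were 1931 in female tumour, 426 in female 5-fluorouracil, 428 in female cisplatin, 156 in female 5-fluorouracil against PBS, 1332 in female paclitaxel against PBS, 97 in female cisplatin against PBS, 117 in female paclitaxel against 5-fluorouracil, 5624 in male tumour, 497 in male paclitaxel, 3968 in male cisplatin, 396 in male 5-fluorouracil against PBS, 1272 in male paclitaxel against PBS, 422 in male cisplatin against PBS, 0 in male paclitaxel against 5-fluorouracil, 0 in male cisplatin against paclitaxel, 1044 in male against female PBS and 33 in the tumour interaction. Without the 19 libraries of high GC slope, which leaves fewer samples, they were 1654 in female tumour, 1 in female paclitaxel, 906 in female cisplatin, 722 in male paclitaxel, 3407 in male cisplatin, 34 in male 5-fluorouracil against PBS, 10 in male paclitaxel against PBS, 54 in male cisplatin against PBS, 0 in male paclitaxel against 5-fluorouracil and 0 in male cisplatin against paclitaxel. The correlation of drug and tumour effects was -0.629 for male 5-fluorouracil and -0.426 for male paclitaxel (-0.299 before) with the covariate, and -0.504 for female 5-fluorouracil (-0.439), -0.268 for female paclitaxel (-0.145), -0.528 for female cisplatin (-0.447) and -0.497 for male paclitaxel without those libraries.

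Genes that changed direction did so in male paclitaxel. With the covariate they were Dld 0.107 (-0.750), Mapre1 0.054 (-0.446), Nr1d2 0.097 (-0.807), Rrm2b 0.027 (-0.739), Tbcb -0.059 (0.453), Tubg1 -0.028 (0.396), mt-Atp8 0.364 (-1.797), mt-Nd2 0.485 (-1.799) and mt-Nd6 0.277 (-1.331). Without the libraries of high GC slope they were Decr1 0.090 (-0.595), Dld 0.112 (-0.750), Emcn 0.042 (-0.558), Foxo4 -0.016 (0.311), Smad2 0.054 (-0.477), Styx-ps 0.845 (-4.174), Tbca 0.044 (-0.760), mt-Atp8 0.419 (-1.797), mt-Nd2 0.486 (-1.799) and mt-Nd6 0.183 (-1.331). In parentheses is the reported log2 change.

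Gene lists changed direction as follows, with the adjusted p of the setting and in parentheses the reported one. With the covariate: male 5-fluorouracil mitochondrially encoded 0.000177 (0.245), ribosomal 8.63e-06 (0.954), male paclitaxel mitochondrially encoded 3.25e-05 (0.0065), ribosomal 4.79e-18 (0.855), tubulins 0.0312 (0.689), the 5-fluorouracil interaction mitochondrially encoded 0.0102 (0.0209), tubulins 0.0185 (0.934), the paclitaxel interaction mitochondrially encoded 0.000723 (0.00692), ribosomal 8.6e-14 (0.684), tubulins 0.0373 (0.762) and the cisplatin interaction mitochondrially encoded 0.00561 (0.0532), ribosomal 0.00939 (0.179). Without the libraries of high GC slope: female paclitaxel mitochondrially encoded 0.0385 (0.861), male 5-fluorouracil mitochondrially encoded 0.0385 (0.245), ribosomal 0.0385 (0.954), male paclitaxel mitochondrially encoded 0.0427 (0.0065), ribosomal 2.68e-08 (0.855), the 5-fluorouracil interaction collagens 0.0289 (0.194), heat shock 0.722 (0.0457) and the paclitaxel interaction IL-6/STAT3 0.00963 (0.823), mitochondrially encoded 0.467 (0.00692), ribosomal 0.000444 (0.684).

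Of 44 lists, the number called with an estimated correlation, given before the number called with the preset one, was 2 of 12 in female tumour, 4 of 20 in female 5-fluorouracil, 1 of 16 in female paclitaxel, 1 of 18 in female cisplatin, 1 of 18 in male tumour, 0 of 17 in male 5-fluorouracil, 0 of 7 in male paclitaxel, 1 of 20 in male cisplatin, 0 of 15 in the tumour interaction, 0 of 13 in the 5-fluorouracil interaction, 0 of 8 in the paclitaxel interaction, 0 of 9 in the cisplatin interaction and 3 of 8 in male against female PBS. At the preset correlation, the number with the covariate was 13 in male paclitaxel and 15 in the cisplatin interaction. Without the libraries of high GC slope that number was 18 in male paclitaxel and 14 in the paclitaxel interaction.

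Among the other results of named genes, direction and call held in 849, 814, 894, 921 and 929 with a mean of at least 1, the compared groups alone, quality weights, quantile normalization and the block, and 4, 130, 25, 22 and 15 lost a call while 0, 7, 32, 8 and 7 gained one. With the covariate 793 held, 145 lost and 4 gained a call, and without the libraries of high GC slope 769, 164 and 8. Over all fits that left out a library 13405 held, 1130 lost and 51 gained a call, and 0 changed direction. Among lists, 540 held under quantile normalization (16 lost, 15 gained), 561 with the block (6 and 5), 521 with the covariate (9 and 30), 487 without the libraries of high GC slope (18 and 57) and 404 with an estimated correlation (168 and 0).

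Another pseudocount and DESeq2 were not run. Female paclitaxel simulated without GC slopes recovered 53.7% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes.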

Other observations

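The tests given here were planned, except those that use the GC slope, which were chosen only after the slopes had been seen.

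Muscle of male and female PBS mice differed in fat, blood and polyamine genes (8 male versus 7 female libraries). Of the adipocyte markers 0 of 13 rose and 5 fell (0 and 10 adjusted over the list alone, median -1.73, adjusted p = 3.24e-09, or 0.0446 with an estimated correlation). Of the erythroid markers 5 of 7 rose and 0 fell (7 and 0 adjusted over the list alone, median 1.73, adjusted p = 3.24e-09, or 0.0446 with an estimated correlation). Of the polyamine metabolism genes 4 of 12 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.24, adjusted p = 1.09e-05, or 0.000552 with an estimated correlation). The slow fibre genes had a median of -0.90 (adjusted p = 2.57e-05, or 0.88 with an estimated correlation). Actr3b, an actin-related protein, was higher in males by 3.73 ± 0.24 (adjusted p = 1.8e-20) in 8 of 8 libraries. In all, 305 genes were higher in males and 165 in females. The count of 470 was 876 with the compared groups alone, 1044 with the GC slope as a covariate and 1722 with quality weights.

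Polyamine genes moved with the tumour in males without a shift of their list. Of the polyamine genes 3 of 12 rose and 5 fell (3 and 5 adjusted over the list alone, median -0.41, adjusted p = 0.141, or 0.316 with an estimated correlation), with spermine oxidase (Smox) at -1.92 ± 0.26 and the decarboxylase Amd1, which shares reads with copies, at -2.57 ± 0.38. Smox rose by 1.66 ± 0.26 under 5-fluorouracil and by 1.52 ± 0.26 under cisplatin in males.

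Across genes, the female effect was smaller than the male effect for genes called in males, with a slope of 0.569 for the tumour, 0.385 for 5-fluorouracil and 0.456 for cisplatin. Of the genes called in males, 3397 of 3617, 2549 of 3233 and 1783 of 2203 had the same sign in females. These genes were picked in males, which by itself lowers a slope.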
